A study of Mus musculus with 15 samples.

How the data were processed

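RNA of mouse NIH 3T3 fibroblasts was measured on 15 Affymetrix MG_74Av2 oligonucleotide arrays. The cells carried a metallothionein-promoter plasmid, which zinc switches on, with a human C/EBPα, C/EBPβ, C/EBPδ or C/EBPε cDNA or with no insert. C/EBPs are bZIP transcription factors of differentiating fat, liver and myeloid cells. Per the labels, polyclonal transfectants were selected with an antibiotic, induced with zinc sulphate for 16 h in triplicate, and lysed for total RNA. The groups, 3 arrays each, are called vector, CEBPA, CEBPB, CEBPD and CEBPE after the titles, and all arrays came from zinc-treated cells.

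The deposited values are linear intensity per probe set, made by the authors with Microarray Suite 5 after scanning. All are above 0, and the 2% trimmed mean was 2501.12 to 2501.39 on every array, which shows that the authors had scaled the arrays to a common mean. Array medians still ranged from 992.25 to 1149.7. No detection calls come with the values, so the labels' filter on probe sets called absent was replaced by a filter on signal. The values carry no counts, and the number of arrays limits the precision.

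Of 12488 probe sets, 66 controls were left out. Each array was divided by the median of its remaining 12422 probe sets and multiplied by the mean of the 15 medians. Scaled values under the pooled 20th percentile (189.652 units) were raised to it and log2 was taken. A probe set was tested if it exceeded the pooled median (1092.06 units) on at least 3 of the 15 arrays, which 6963 probe sets for 5338 genes did. Symbols came from the array annotation in the reference, where 10833 probe sets named 1 gene, 396 named several and 1193 named none.

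All groups entered 1 fit of limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 1 coefficient per group. Each C/EBP and the mean of the 4 were set against vector, and the C/EBPs against each other. The moderated test was two-sided, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested, within each contrast, with a threshold of 0.05. Moderated F-tests covered any difference among the 5 groups and among the 4 C/EBPs. Errors beside log2 differences are standard errors of the fit, and those beside signals are SD over 3 arrays. The p-values measure the spread between these cultures, which the labels describe as triplicate clones. The labels also call the transfectants polyclonal, and whether the 3 arrays of a group came from separate transfections was not established here. If they share 1 transfection, the p-values do not cover the spread between transfections. A difference between transfected pools could then not be told apart from an effect of the C/EBP.

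Of 30 gene lists, the 26 with at least 5 measured genes were tested with limma's camera, with the correlation between genes preset at 0.01 and Benjamini-Hochberg over the lists. The test was repeated with the correlation estimated for each list. A gene was read by its brightest tested probe set. The text names the C/EBP genes, the 10 largest rises and 10 largest falls per contrast among genes past the threshold whose arrays lay on 1 side of all vector arrays (filled to 5 by unadjusted p where fewer passed), the 10 genes with the largest range among the C/EBPs, and up to 4 members of a list. Lists, groups, tests, this rule and the alternatives were fixed before the data were examined, apart from 1 alternative, the test of granulocyte genes and the tests of explanations in the closing section.

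On simulated data with the same 6963 probe sets, the fit recovered 33.6% of the changes of 1.5-fold, 70.8% of those of 2-fold and 90.4% of those of 3-fold, and called 0.0858% of the unchanged probe sets. All 25 changed lists, in which every member was raised 1.5-fold, were recovered, and 0 of 125 unchanged lists were called. For the shares of probe sets, 200 were changed in each simulated data set, in CEBPA alone. These shares need not hold where another number of probe sets changes, nor the recovery of lists where only some members move. In these simulated data each gene varied on its own and the lists were random. They therefore do not show how often camera calls unchanged lists of correlated genes. Overlaps between contrasts were set against independent lists and against 100 simulated data sets in which unchanged groups shared the vector arrays.

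Alternatives were other scalings (quantile normalization, none, the median log2 ratio to the mean array), other floors and filters, no trend, array weights, the replicate number as a block, only the groups of a contrast, leaving out each array in turn, the labels' univariate F-test, a rotation test for lists (fry) and a threshold of 0.1 for overlaps. Leaving out the 5 arrays numbered 1 was added after seeing the data. Ranges and highest or lowest p-values over the alternatives exclude the fits that left out 1 array. Correlations between log2 values ranged from 0.929 to 0.965 within groups and from 0.880 to 0.961 between groups.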

Results

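Expression was measured in NIH 3T3 cells, an immortal mouse fibroblast line, that expressed 1 of 4 C/EBPs or carried the empty vector, with 3 arrays in each of the 5 groups. The question put by the labels was which genes differ between the 5 sets. All cells had received zinc for 16 h, so each comparison sets a C/EBP-expressing culture against a vector culture under the same metal treatment. Deposited signals ran from 0.5 to 256544 units per probe set. The lowest array median was 992.25 and the highest 1149.7.

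Across the 5 groups, 1149 of the 6963 probe sets differed at an adjusted p of 0.05, and 1516 at 0.1. The labels give 158 genes at a false discovery share of 10%, of which 117 reached 0.001 in a univariate F-test. On the values used here, that F-test gave 565 probe sets at 0.001, 986 after Benjamini-Hochberg at 0.05 and 1380 at 0.1. The labels' list was drawn after another filter and under a limit on false discoveries set with 95% probability, so the counts are not of 1 kind. Without the 5 arrays numbered 1, which deviated together in all groups (alternative added after seeing the data), the moderated F-test called 685, and with array weights 2442. Fewer arrays entered the fit that gave 685, so the drop does not by itself show that calls rested on the arrays left out. With all arrays and the replicate number as a block the count was above 1149, as given in the part on processing.

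**Figure D1:**
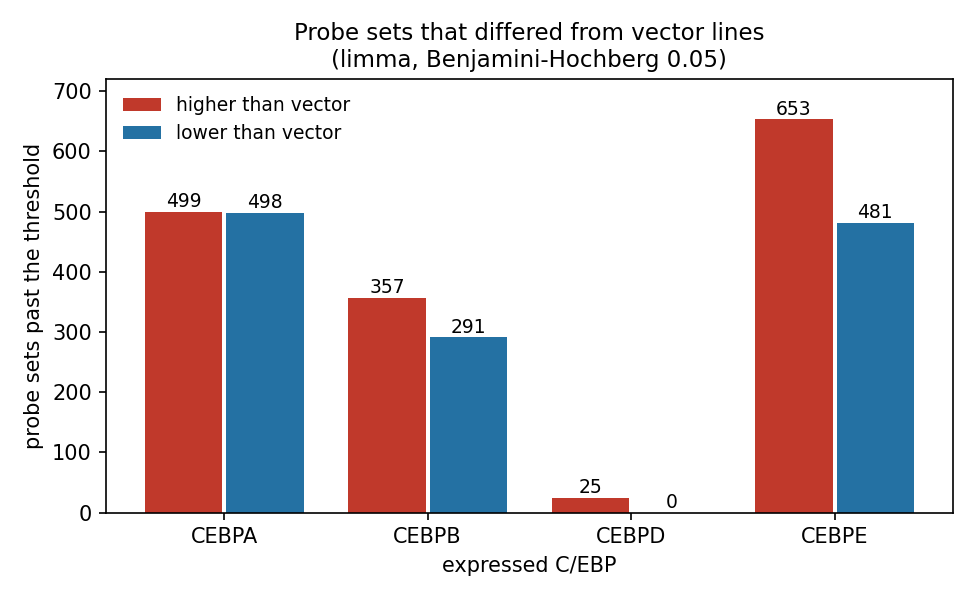
Number of probe sets past the threshold in each C/EBP group against vector (limma, Benjamini-Hochberg 0.05; 3 arrays per group). Red bars count probe sets higher than vector and blue bars those lower; CEBPD has 25 higher and 0 lower, against 653 and 481 for CEBPE.

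The family itself was read through its mouse probe sets. With the settings used here Cebpb and Cebpd did not pass in any C/EBP group. Cebpb read 14200 ± 4247 in vector and 9575 to 12110 on average in the C/EBP groups, and Cebpd read 6691 ± 1337 in vector and 5454 to 7001. Cebpg, a family member without a transactivation domain, fell in CEBPE from 3824 ± 232 to 2162 ± 336 (log2 -0.83, SE 0.16, adjusted p = 0.00198). It also fell in CEBPA (log2 -0.62, adjusted p = 0.0148), where the call was lost without CEBPA replicate 2 (adjusted p = 0.0724). In CEBPB Cebpg read -0.48 and was not called (adjusted p = 0.0740, range over the alternatives 0.0306 to 0.148). Cebpa lay under the signal filter at 544 ± 84.4 in vector and 724 to 794.6 in the C/EBP groups, and with no filter it was not called. Cebpe is not named on this array. The expressed cDNAs were human, and whether a mouse probe set reads them was not tested, so these signals do not measure the level of the introduced factors. The list of 7 family genes had 4 measured members, 1 of which was Ddit3, and was too small for camera. Cebpg and Ddit3 were the 2 called lower in CEBPA and in CEBPE, and Ddit3 the 1 in CEBPB. With no filter the list had 5 members, and camera called it lower in CEBPA and CEBPE (adjusted p = 0.0342 and 0.01225). It was not called in CEBPB or CEBPD (0.118 and 0.6115), nor in CEBPA or CEBPE with an estimated correlation (0.358 and 0.390).

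In CEBPA cells, the largest rises included genes of lipid handling and the acute phase. Lpl, the lipase that releases fatty acids from lipoproteins, rose 38.6-fold (log2 5.27, SE 0.23), from 253.9 ± 33.4 to 9839 ± 1560 (SD, n = 3). Hp, the haemoglobin-binding acute phase protein haptoglobin, rose 28.0-fold to 38750 ± 8481. Cd1d1, a lipid-presenting relative of MHC class I, rose 46.1-fold to 9731 ± 485, with 2 of its 3 vector arrays at the floor. Pparg, the nuclear receptor that drives fat cell differentiation, was at least 15.7-fold higher and the transglutaminase gene Tgm3 at least 20.3-fold higher, all vector arrays being at the floor; with no floor the Pparg call was lost (adjusted p = 0.0619, range over the alternatives 1.08e-09 to 0.0619). S100a8, which encodes a calcium-binding protein of neutrophils, rose 13.0-fold, and Serpini1, Abcd2, Nnmt and Kng1 rose between 9.13-fold and 10.3-fold, with 2 vector arrays at the floor for Serpini1 and 1 for Abcd2.

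The largest falls in CEBPA cells included stress genes. Gadd45g, a growth arrest gene induced by stress, fell from 16230 ± 4916 to 745 ± 144 (log2 -4.42, SE 0.27). The Hsp70 genes Hspa1b and Hspa1a, near-identical copies whose probe sets are not independent, changed by -4.12 and -4.08 on the log2 scale, and the co-chaperone gene Dnajb1 by -3.37. Fos, the early-response subunit of AP-1, fell from 9784 ± 3065 to 819 ± 205 (log2 -3.56, SE 0.21). Vwf, Pea15a, Fam117a, Zfand2a and Msh3 completed the 10 largest falls, at log2 -3.38, -3.23, -3.23, -2.87 and -2.82, with 2 of 3 CEBPA arrays at the floor for Vwf.

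Of 14 measured heat shock genes, 12 fell in CEBPA cells, 2 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 2.79e-15, and adjusted p = 0.0356 with an estimated correlation). Cryab fell 6.75-fold and Hsph1 3.87-fold. Of 24 immediate early genes, which respond within minutes to growth factors and stress, 11 fell, 1 rose and 12 did not pass (15 fell and 1 rose adjusted over the list alone; adjusted p = 8.13e-10, and 0.0471 with an estimated correlation); Dusp1 fell 3.70-fold, Btg2 3.35-fold, and Dusp6 rose 1.75-fold. Of 7 genes of the metallothionein and zinc response, 4 fell over all genes and over the list alone, and 3 did not pass (adjusted p = 2.33e-04, and 0.0299 with an estimated correlation). The member that moved most, Hmox1, encodes heme oxygenase, a stress enzyme; it fell from 99720 ± 2202 to 17160 ± 2492. The zinc exporter gene Slc30a1 fell 1.89-fold and the metallothionein gene Mt2, from 155300 ± 17060 to 101100 ± 21050, 1.55-fold, a call lost without CEBPA replicate 1 (adjusted p = 0.0541) and with no filter (0.0646).

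Further lists called lower lost the call with an estimated correlation. Growth arrest and p53 target genes had 8 falls and 2 rises among 17, and 9 and 2 adjusted over the list alone (adjusted p = 4.75e-04; adjusted p = 0.267 with an estimated correlation). The unfolded protein and integrated stress response had 6 falls and 2 rises among 23, and 10 and 3 over the list alone (adjusted p = 0.00299; adjusted p = 0.267 with an estimated correlation); its falls included Ppp1r15a, 5.71-fold, and Ddit3, 4.52-fold. Among 12 contractile genes, 6 fell and 8 over the list alone, with smooth muscle actin Acta2 down 2.96-fold (adjusted p = 9.18e-05; adjusted p = 0.113 with an estimated correlation). Among 11 matrix proteases and inhibitors, 3 fell and 5 over the list alone, and Plat and Plaur, the tissue plasminogen activator and urokinase receptor genes, fell 5.36-fold and 4.09-fold (adjusted p = 4.75e-04; adjusted p = 0.0901 with an estimated correlation).

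Lists called higher in CEBPA cells were of lipid and defence genes. Of 8 acute phase and innate defence genes, 4 rose, 5 over the list alone and none fell (adjusted p = 1.73e-04, and 0.0299 with an estimated correlation); besides Hp, Ptx3 rose 2.82-fold and Cp 2.27-fold. Of 16 cholesterol synthesis genes, 9 rose, 9 over the list alone and 0 fell, with Nsdhl up 2.74-fold and Hmgcs1 2.25-fold (adjusted p = 7.39e-08; adjusted p = 0.113 with an estimated correlation). Of 15 adipocyte differentiation genes, 5 rose and 6 over the list alone (median 0.31, adjusted p = 2.10e-04; adjusted p = 0.113 with an estimated correlation). With no filter, 5 of 25 adipocyte genes rose and 1 fell, and the list median was 0.14 (adjusted p = 0.0132; adjusted p = 0.276 with an estimated correlation). The fat cell marker Fabp4 lay under the filter, at 207 ± 185 in vector and 237 ± 104 in CEBPA. Dgat1, for the last step of triglyceride synthesis, rose 2.49-fold. In all, 499 probe sets were higher and 498 lower in CEBPA (limma), and 153 and 167 of them by more than 2-fold. The CEBPA and vector arrays did not overlap for 28.1% of the probe sets, where chance gives 10%. The higher share of 50.1% became 47.7% when arrays were scaled by their median ratio to the mean array. Without the arrays numbered 1 the count fell from 997 to 642.

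In CEBPB cells Vwf, which encodes von Willebrand factor, fell from 2336 ± 365 to 342 ± 194 (log2 -2.77, SE 0.44; 1 CEBPB array at the floor), Gadd45g from 16230 ± 4916 to 3078 ± 967 (log2 -2.40, SE 0.27) and Fos to 1951 ± 316 (log2 -2.29, SE 0.21). Hspa1a fell by 2.32 on the log2 scale, Ppp1r15a, which restores translation after stress, by 2.05, and Wwc1 and Zfand2a by 2.20 and 1.99. Dnajb1 fell from 25800 ± 2805 to 6449 ± 806. The interleukin gene Il11 fell by 2.20, a call lost without CEBPB replicate 3 (adjusted p = 0.0655). Met, the receptor for hepatocyte growth factor, rose 6.82-fold and Mvd, an enzyme of cholesterol synthesis, 6.39-fold. Abcb10, Nnmt, Echs1 and Gsdme rose 5.75-fold, 4.61-fold, 4.35-fold and 3.65-fold, and Met and Gsdme each had 1 vector array at the floor. H2-M2 rose 4.14-fold and Lpl 3.49-fold, but with the floor at the 40th percentile neither was called (adjusted p = 0.196 and 0.252, the highest over the alternatives, the lowest being 4.27e-05 and 3.28e-06). Lpl was also not called with only CEBPB and vector in the fit (adjusted p = 0.0509), and its other probe set read 0.04 on the log2 scale (adjusted p = 0.955); that of Gsdme read 0.40.

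Calls that rested on single arrays completed the named genes of CEBPB. U2surp (5.93-fold higher, with 2 of 3 vector arrays at the floor) was lost without vector replicate 2 or 3 or CEBPB replicate 2 or 3 (adjusted p = 0.0539, 0.0732, 0.0741 and 0.0626), and Mknk1 (3.29-fold higher) without vector replicate 1 or 3 or CEBPB replicate 2 or 3 (0.0514, 0.0906, 0.0988 and 0.0772). Itga7 (4.07-fold lower) was lost without vector replicate 1, 2 or 3 or CEBPB replicate 1 or 3 (0.0525, 0.0525, 0.0800, 0.0540 and 0.0536), and without the arrays numbered 1 (adjusted p = 0.166, range over the alternatives 9.39e-04 to 0.166). With no filter U2surp and Mknk1 were not called (adjusted p = 0.0698 and 0.0790, the highest over the alternatives, the lowest being 8.60e-04 and 0.00163).

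Of 14 heat shock genes 10 fell in CEBPB, and 12 over the list alone, with Hspa1b down 2.86-fold and Hsph1 2.45-fold (adjusted p = 2.23e-14; adjusted p = 0.0643 with an estimated correlation). Of 24 immediate early genes 9 fell, and 9 over the list alone (adjusted p = 4.34e-09; adjusted p = 0.0829 with an estimated correlation). The zinc response list had 3 falls among 7 and 4 over the list alone, with Hmox1 down 3.63-fold and Slc30a1 2.03-fold (adjusted p = 2.32e-05, and 0.0219 with an estimated correlation). Mt2 fell 1.77-fold to 87700 ± 7597. Of 16 cholesterol synthesis genes 8 rose, and 10 over the list alone (adjusted p = 2.54e-09; adjusted p = 0.130 with an estimated correlation). Of 37 extracellular matrix genes 10 rose and 1 fell, and 14 and 2 over the list alone (adjusted p = 7.22e-04; adjusted p = 0.316 with an estimated correlation). The proteoglycan gene Dcn rose 3.09-fold, Postn 2.84-fold and the collagen gene Col3a1 2.24-fold.

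Other lists of CEBPB lost their calls with an estimated correlation. Lower were growth arrest genes, with 5 falls and 2 rises among 17 and 8 and 2 over the list alone (adjusted p = 0.00815; adjusted p = 0.423 with an estimated correlation), and the unfolded protein and integrated stress response, with 6 falls and 1 rise among 23 and 6 and 2 over the list alone (adjusted p = 0.00373; adjusted p = 0.316 with an estimated correlation). Contractile genes had 2 falls among 12 and 2 over the list alone (adjusted p = 0.00979; adjusted p = 0.340 with an estimated correlation), a list call also lost with array weights (adjusted p = 0.0761). Matrix proteases and inhibitors had 2 falls among 11, and 3 falls and 1 rise over the list alone (adjusted p = 0.0212; adjusted p = 0.316 with an estimated correlation); this call was lost without CEBPB replicate 1 (adjusted p = 0.0582), with no filter (0.0781) and with array weights (0.0514). Wnt, Notch and TGF-beta pathway genes had 4 falls among 20 and 4 over the list alone, led by Id2 and Id3, inhibitors of differentiation, down 2.58-fold and 2.56-fold (adjusted p = 0.0237; adjusted p = 0.211 with an estimated correlation). With no filter the Wnt, Notch and TGF-beta call was lost (adjusted p = 0.191). The circadian list had 1 fall among 14 and 1 over the list alone, Nr1d1, a repressor of the clock, down 2.28-fold (adjusted p = 0.0241; adjusted p = 0.340 with an estimated correlation); the list call was lost without vector replicate 1 or CEBPB replicate 1 (adjusted p = 0.0581 and 0.0914) and without the arrays numbered 1 (0.141). Since a clock gene was known from this study when the list was written, its direction is not independent evidence. Oxidative phosphorylation had 4 rises among 41 and 9 over the list alone (adjusted p = 0.00823; adjusted p = 0.647 with an estimated correlation), a call lost without vector replicate 1 (adjusted p = 0.0649) and in the rotation test fry (0.139).

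In CEBPB, 357 probe sets were higher and 291 lower (limma), with 83 and 91 beyond 2-fold, and 27.1% of the probe sets had arrays that did not overlap with vector (chance 10%). The higher share of 55.1% became 49.0% when arrays were scaled by their median ratio to the mean array. The count of 648 became 420 without vector replicate 3, 418 without CEBPB replicate 2, 372 without CEBPB replicate 3, 348 without the arrays numbered 1 and 1576 with array weights.

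CEBPD cells had the fewest called probe sets, and every called probe set was higher. Lpl rose 6.44-fold (log2 2.69, SE 0.23), from 253.9 ± 33.4 to 1648 ± 327 (its other probe set read 0.75 on the log2 scale, adjusted p = 0.630), Cd1d1 6.35-fold to 1340 ± 72.5 with 2 of 3 vector arrays at the floor, and Hp 3.76-fold to 5148 ± 810. Aldh3a1, an aldehyde dehydrogenase, rose 2.60-fold, the neutrophil chemokine gene Cxcl5 2.48-fold and the epithelial growth factor gene Fgf7 2.46-fold. Ereg and Ptx3 rose 2.93-fold and 2.44-fold, calls lost without the arrays numbered 1 (adjusted p = 0.0564 and 0.0673, the highest over the alternatives, the lowest being 2.51e-05 and 1.73e-04). Xdh rose 2.31-fold, a call lost without vector replicate 1 or CEBPD replicate 2 (adjusted p = 0.0708 and 0.0833) and with no filter (0.0982, the highest over the alternatives, the lowest being 2.46e-05), where Ptx3 was not called either (0.0517). H2-M2 read 3.65-fold higher, a call lost in 9 of the 15 fits that left out 1 array, with adjusted p-values from 0.0514 to 0.272: those without vector replicates 1 and 3, CEBPA replicates 1 and 3, CEBPB replicate 2, CEBPD replicates 2 and 3, and CEBPE replicates 1 and 3. Over the alternatives its adjusted p ranged from 0.00530 to 0.881.

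No fall passed in CEBPD (0 probe sets by limma, with 443 at an unadjusted p under 0.05 in either direction). The smallest p-values on the lower side belonged to Hspg2 (log2 -1.26, adjusted p = 0.113), Ank3 (-0.95, 0.139), Kcnn4 (-0.58, 0.182), Cyb5r1 (-0.62, 0.208; its other probe set read 0.09) and Nr1d1 (-0.54, 0.261). Without CEBPD replicate 3 Hspg2 passed (adjusted p = 3.54e-04). Array weights brought Ank3 and Kcnn4 past the threshold (adjusted p = 0.0277 and 0.0258), and quantile normalization or no further scaling brought Cyb5r1 past it (0.0415 and 0.0492), while without the arrays numbered 1 the adjusted p-values of Hspg2, Ank3, Kcnn4 and Cyb5r1 were 0.559, 0.653, 0.559 and 0.556, the highest over the alternatives.

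None of the 14 heat shock genes passed in CEBPD, over all genes or over the list alone, and the list median was -0.23 (camera adjusted p = 2.77e-04; adjusted p = 0.680 with an estimated correlation). The 7 zinc response genes likewise had no call on either count, with a median of -0.26 (adjusted p = 0.00558; adjusted p = 0.0790 with an estimated correlation). Hmgcs1 was the 1 of 16 cholesterol synthesis genes called, 1.57-fold higher, with 2 called over the list alone (adjusted p = 0.00558; adjusted p = 0.728 with an estimated correlation); its own call was lost without vector replicate 1 or 3 or CEBPD replicate 2 or 3 (adjusted p = 0.0697, 0.103, 0.107 and 0.0747), and that of the list without vector replicate 1 (0.0653). Without the arrays numbered 1 neither Hmgcs1 nor the list was called (adjusted p = 0.152 and 0.0644), nor was Hmgcs1 with only CEBPD and vector in the fit (0.128). Of 8 acute phase genes 2 rose, Hp and Ptx3, and 2 over the list alone (adjusted p = 0.00558; adjusted p = 0.0790 with an estimated correlation); this list call was lost without vector replicate 2 or CEBPD replicate 1 (adjusted p from 0.138 to 0.154), without the arrays numbered 1 (0.0732), with no filter (0.0853) and with array weights (0.137). Among 32 G2 and mitosis genes none was called on either count, and the list median was 0.12 (adjusted p = 0.0312; adjusted p = 0.728 with an estimated correlation); the list call was lost without vector replicate 1 or 3 or CEBPD replicate 2 (adjusted p from 0.133 to 0.184) and without the arrays numbered 1 (0.0732). The rotation test fry did not call the heat shock, cholesterol synthesis or G2 and mitosis lists in CEBPD (adjusted p = 0.301, 0.378 and 0.655).

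The CEBPD count was 25 probe sets higher and 0 lower, 15 of them by more than 2-fold. Arrays did not overlap with vector for 11.7% of the probe sets, against 10% by chance. The count was 13 without CEBPD replicate 2, 11 without the arrays numbered 1, 15 when only CEBPD and vector entered the fit, 39 under quantile normalization and 74 with array weights.

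In CEBPE cells the largest falls were in heat shock, growth arrest and early-response genes and Vwf. Hspa1a fell from 27480 ± 2069 to 750 ± 454 (log2 -5.40, SE 0.32), Hspa1b from 79960 ± 6176 to 3600 ± 476 (log2 -4.48, SE 0.14), and Dnajb1 from 25800 ± 2805 to 2666 ± 694 (log2 -3.31). Gadd45g fell to 603 ± 241 (log2 -4.78), Gadd45b by 3.92, Fos to 618.5 ± 33.6 (log2 -3.94), and Trib3, a pseudokinase of the stress response, by 3.67, with 1 CEBPE array at the floor. Vwf was at least 12.2-fold lower, all CEBPE arrays being at the floor, and Fam117a (1 CEBPE array at the floor) and Zfand2a fell 8.97-fold and 7.86-fold.

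Dcn rose the most in CEBPE, 9.77-fold from 3052 ± 461 to 30100 ± 6585 (log2 3.29, SE 0.17), followed by the transcript U90926, 7.55-fold. Aldh3a1 rose 5.83-fold to 5168 ± 238, Cxcl5 5.03-fold and Fgf7 4.76-fold. Echs1, an enzyme of fatty acid oxidation, rose 6.13-fold, Mvd 6.10-fold, H2-M2 6.03-fold, the growth-regulatory gene Slfn2 5.47-fold (1 vector array at the floor) and Nnmt 4.79-fold. The other, less bright probe set of Slfn2 read 3.22 on the log2 scale. Lpl was also higher than vector in CEBPE, at 1025 ± 222 (its other probe set read 0.47 on the log2 scale, adjusted p = 0.310), and Cd1d1 and Hp were higher by 1.06 and 0.89 on the log2 scale.

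**Figure D2:**
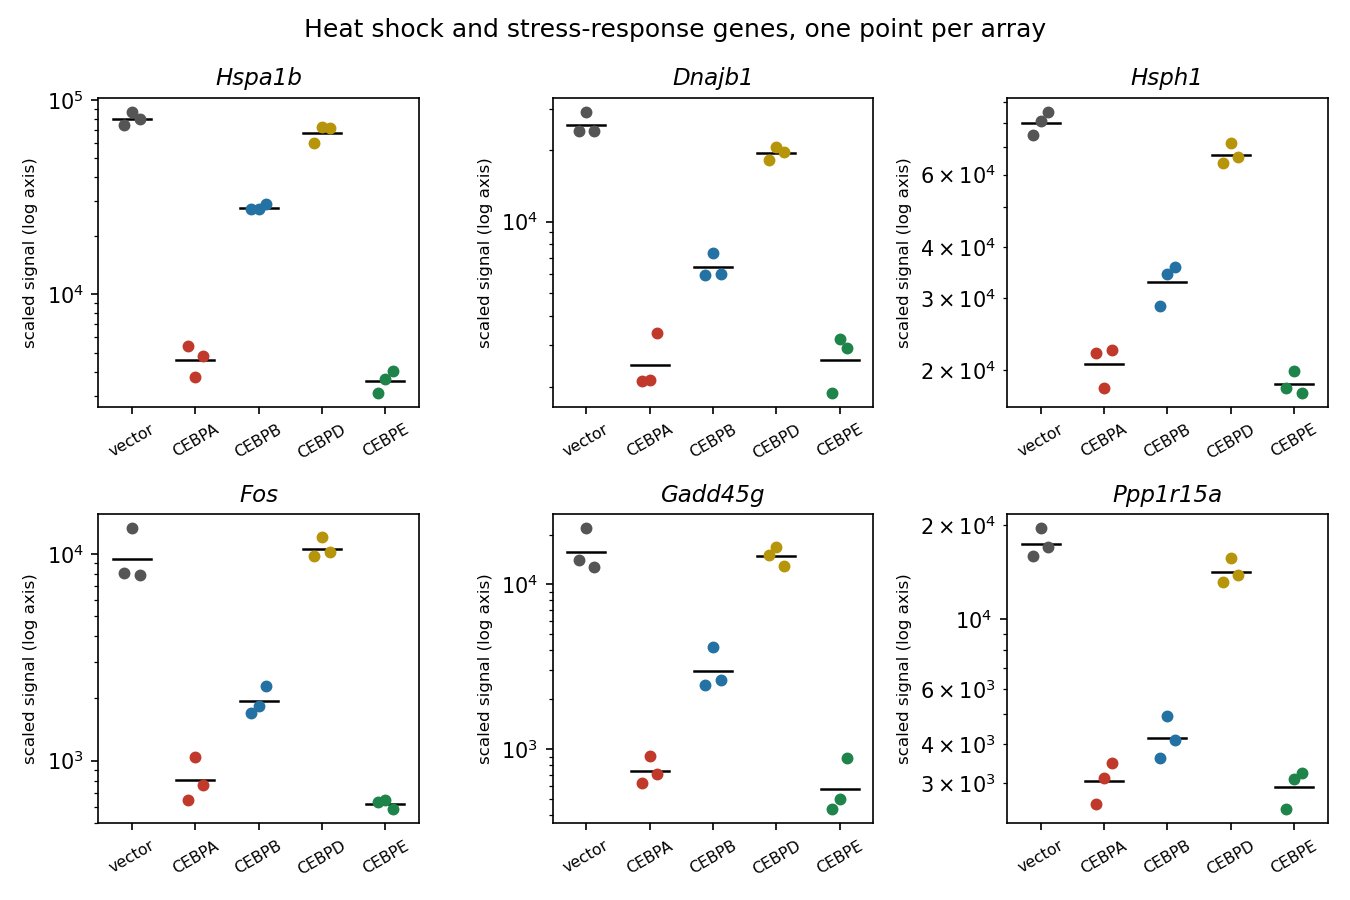
Scaled signal (log axis) of 6 heat shock and stress-response genes; each point is 1 array, coloured by group, and black bars are geometric means of 3 arrays. In each panel the CEBPA, CEBPB and CEBPE points lie under all vector points, and CEBPD points lie above all points of these 3 groups. The CEBPD points also lie under all vector points for Hspa1b, Dnajb1, Hsph1 and Ppp1r15a, and overlap them for Fos and Gadd45g. For Hspa1b the vector mean was 79960 and the CEBPE mean 3600.

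Of 14 heat shock genes 11 fell in CEBPE, and 13 over the list alone (adjusted p = 1.28e-18, and 0.0310 with an estimated correlation). The zinc response list had 3 falls among 7 and 4 over the list alone (adjusted p = 2.98e-04, and 0.0310 with an estimated correlation); Hmox1 fell 6.87-fold, and Slc30a1 1.58-fold, a call lost without vector replicate 1 or 3 or CEBPE replicate 2 (adjusted p = 0.0575, 0.0508 and 0.0567) and without the arrays numbered 1 (0.104, range over the alternatives 0.00773 to 0.104). Of 24 immediate early genes 12 fell and 1 rose, and 13 and 1 over the list alone (adjusted p = 4.00e-09; adjusted p = 0.0819 with an estimated correlation). Of 23 genes of the unfolded protein and integrated stress response 10 fell and 3 rose, and 13 and 4 over the list alone, with Ppp1r15a down 5.94-fold and Asns, asparagine synthetase, 1.91-fold (adjusted p = 1.02e-05; adjusted p = 0.129 with an estimated correlation). Growth arrest and p53 target genes had 9 falls and 3 rises among 17, and 10 and 3 over the list alone (adjusted p = 2.84e-04; adjusted p = 0.343 with an estimated correlation). Contractile genes had 3 falls among 12, and 3 falls and 1 rise over the list alone (adjusted p = 0.0179; adjusted p = 0.432 with an estimated correlation), a list call lost without vector replicate 2 (adjusted p = 0.0671). Matrix proteases and inhibitors had 2 falls among 11, Plaur and Plat, and 3 over the list alone (adjusted p = 0.00989; adjusted p = 0.208 with an estimated correlation).

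Cholesterol synthesis genes rose in CEBPE in 10 of 16 cases, and 11 over the list alone; Nsdhl rose 3.54-fold and Lss, lanosterol synthase, 3.11-fold (adjusted p = 4.00e-09; adjusted p = 0.129 with an estimated correlation). Among 32 G2 and mitosis genes 1 rose, and 1 over the list alone, with a list median of 0.23 (adjusted p = 0.0455; adjusted p = 0.645 with an estimated correlation). That list call was lost without vector replicate 1 or 3, CEBPA replicate 2 or CEBPE replicate 2 (adjusted p from 0.0519 to 0.116), without the arrays numbered 1 (0.0684), under quantile normalization (0.0519), with the filter at the 70th percentile (0.0768), with only CEBPE and vector in the fit (0.0533) and by fry (0.0574). In all, 653 probe sets were higher and 481 lower in CEBPE (limma), 137 and 185 by more than 2-fold, and 29.8% of the probe sets did not overlap with vector (chance 10%). The higher share of 57.6% became 47.0% when arrays were scaled by their median ratio to the mean array. The count of 1134 became 751 without vector replicate 3, 692 without the arrays numbered 1, 690 with only CEBPE and vector in the fit and 1730 with array weights.

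**Figure D3:**
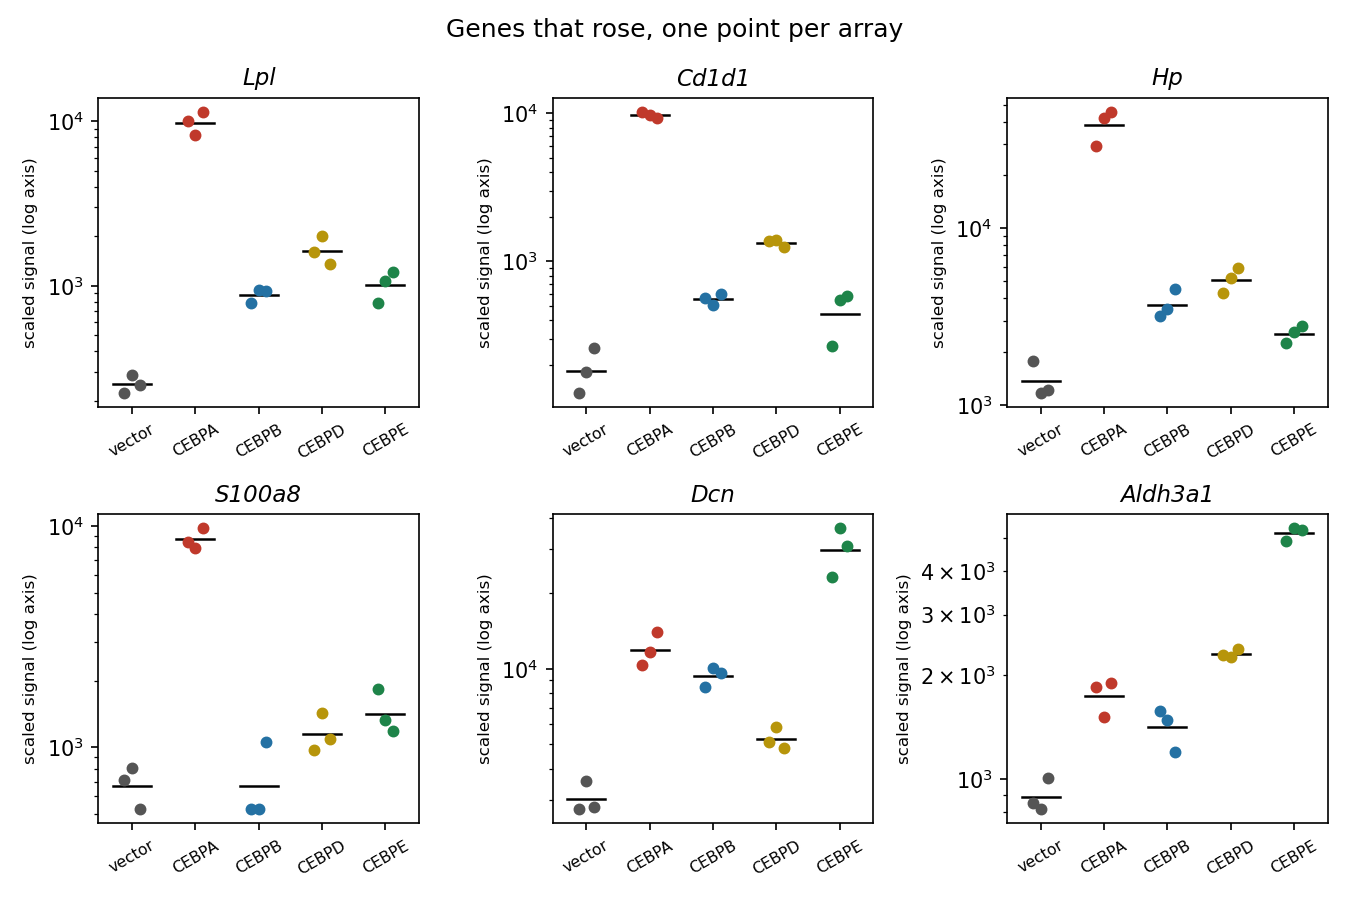
Scaled signal (log axis) of 6 genes that rose in at least 1 C/EBP group; each point is 1 array, coloured by group, and black bars are geometric means of 3 arrays. Lpl, Cd1d1, Hp and S100a8 are highest in CEBPA, and Dcn and Aldh3a1 in CEBPE, where Dcn averaged 30100 against 3052 in vector.

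Taking the 4 C/EBPs as 1 mean against vector, Lpl rose 7.68-fold (log2 2.94, SE 0.18; all 12 C/EBP arrays above the 3 vector arrays; 1.17 on its other probe set), Cd1d1 6.33-fold with 2 vector arrays at the floor, Nnmt 5.04-fold, Hp 4.80-fold, Met 4.44-fold, Dcn 3.79-fold, Abcb10 3.65-fold, Fam20c 3.28-fold and Abcd2 3.24-fold, with 1 vector array at the floor for Met and for Abcd2. H2-M2 rose 4.22-fold, a call lost with the floor at the 40th percentile (adjusted p = 0.0600, range over the alternatives 3.84e-05 to 0.0600). The largest falls were in Hspa1a (log2 -3.03, SE 0.25), Hspa1b (-2.59), Dnajb1 (-2.27), Il11 (-2.16; 3 of 12 C/EBP arrays at the floor), Wwc1 (-2.02), Hmox1 (-1.86), Ppp1r15a (-1.86), the small heat shock protein gene Cryab (-1.79), Dnajb2 (-1.70) and Cyb5r1 (-1.51, and -0.29 on its other probe set). Cebpg read -0.48 (adjusted p = 0.0197), a call lost without vector replicate 2 or 3 (0.0803 and 0.0867) and without the arrays numbered 1 (0.0735, range over the alternatives 0.00673 to 0.0735).

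For this mean, 12 of 14 heat shock genes fell, and 13 over the list alone (adjusted p = 5.54e-17, and 0.0382 with an estimated correlation), and 4 of 7 zinc response genes, 6 over the list alone (4.01e-05, and 0.0262 with an estimated correlation). Cholesterol synthesis had 9 rises among 16 and 10 over the list alone (adjusted p = 4.75e-09; adjusted p = 0.117 with an estimated correlation). Immediate early genes had 10 falls and 1 rise among 24, and 16 and 1 over the list alone (adjusted p = 1.95e-09; adjusted p = 0.0704 with an estimated correlation). Acute phase genes had 4 rises among 8 and 4 over the list alone (adjusted p = 0.0107; adjusted p = 0.0893 with an estimated correlation), a list call lost without vector replicate 2 (0.0768) and with no filter (0.0845). Ribosomal protein genes had no call among 19 on either count and a median of -0.15 (adjusted p = 0.0337; adjusted p = 0.647 with an estimated correlation); quantile normalization, the floor at the 40th percentile and fry ended that call (adjusted p = 0.745, 0.0580 and 0.291), as did leaving out vector replicate 2 or 3, CEBPA replicate 1 or CEBPE replicate 1 (adjusted p from 0.0564 to 0.149).

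For the same mean, adipocyte genes had 3 rises among 15 and 4 over the list alone (adjusted p = 0.0114; adjusted p = 0.285 with an estimated correlation), a list call lost without CEBPA replicate 2 or 3 (0.0699 and 0.0608), without the arrays numbered 1 (0.0620) and with no filter (0.0974). Growth arrest and p53 target genes had 6 falls and 2 rises among 17, and 10 and 3 over the list alone (adjusted p = 0.00219; adjusted p = 0.341 with an estimated correlation); Mdm2, the ligase that degrades p53, fell 1.96-fold. The unfolded protein and integrated stress response had 8 falls and 2 rises among 23, and 9 and 2 over the list alone (adjusted p = 2.98e-04; adjusted p = 0.191 with an estimated correlation), Ddit3 falling 2.68-fold and the disulphide isomerase gene Pdia6 rising 1.77-fold. Contractile genes had 3 falls among 12 and 5 over the list alone (adjusted p = 0.00121; adjusted p = 0.222 with an estimated correlation). Matrix proteases and inhibitors had 2 falls among 11 and 2 over the list alone (adjusted p = 0.00274; adjusted p = 0.135 with an estimated correlation).

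In all, 523 probe sets were higher and 390 lower in the mean of the 4 C/EBPs (limma), with 71 and 80 beyond 2-fold, and 4.06% did not overlap with vector (chance 0.440%). The higher share of 57.3% became 50.3% when arrays were scaled by their median ratio to the mean array. The count of 913 became 603 without vector replicate 1, 500 without vector replicate 3 and 518 without the arrays numbered 1.

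**Figure D4:**
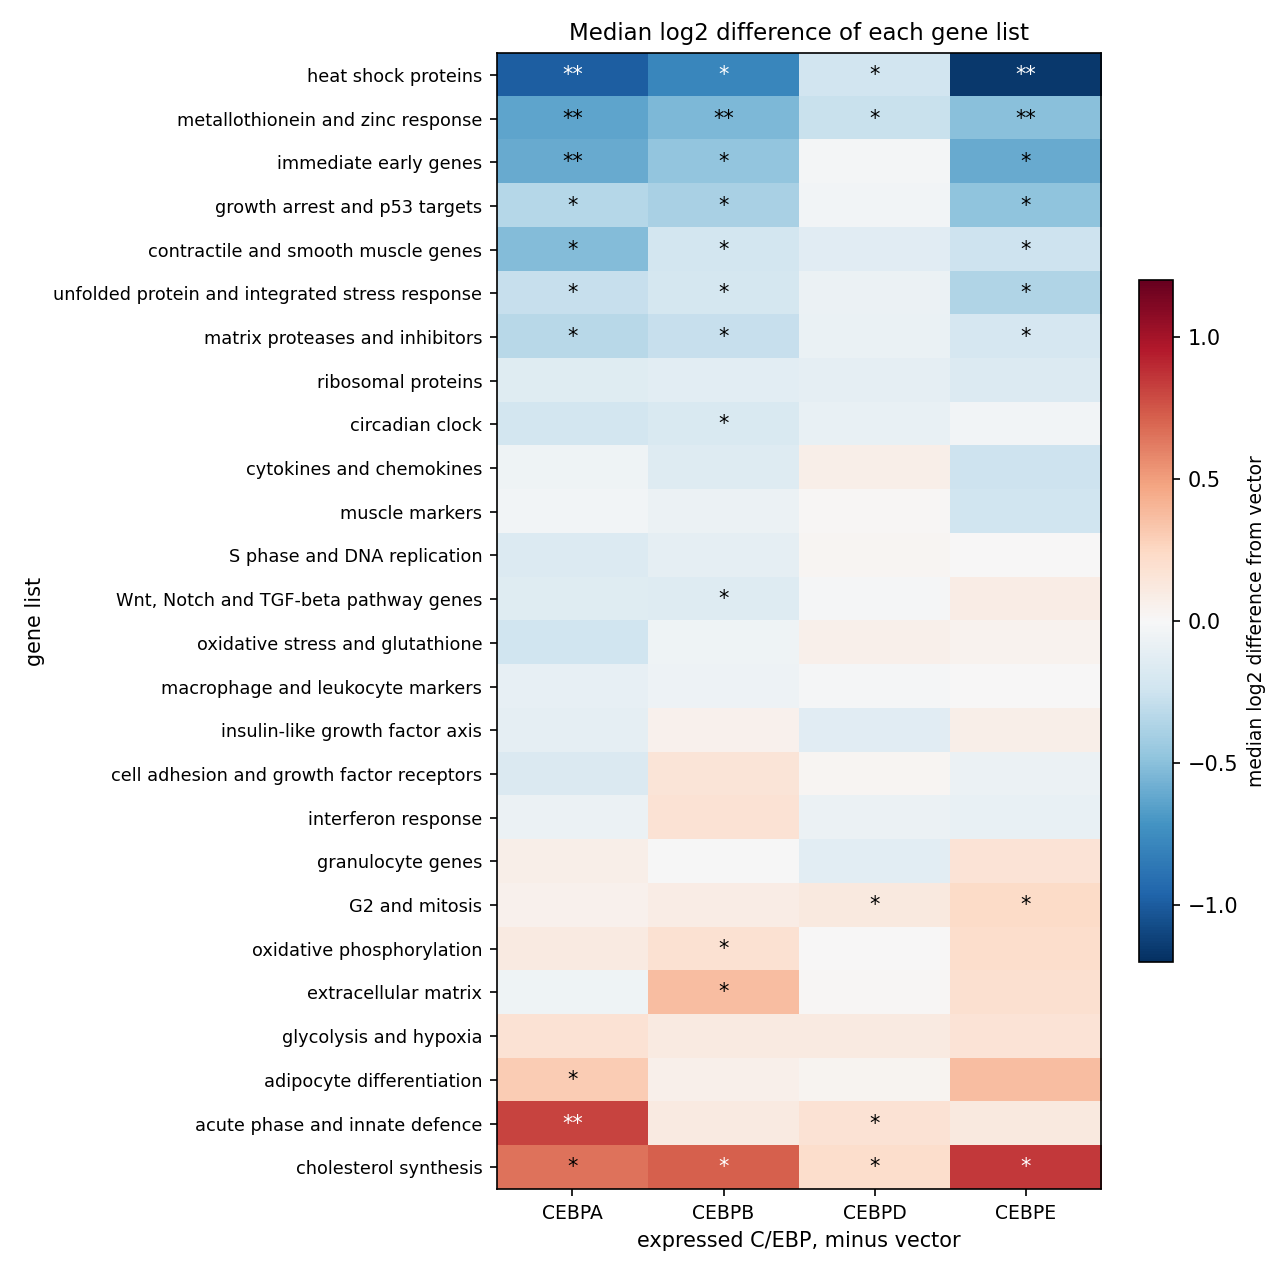
Median log2 difference from vector of the measured members of 26 gene lists (vertical axis) in the 4 C/EBP groups (horizontal axis); blue is lower and red higher than vector. One star marks a camera call with the preset correlation, and a double star a call that also held with an estimated correlation; heat shock genes had medians of -0.99, -0.78, -0.23 and -1.16 in CEBPA, CEBPB, CEBPD and CEBPE.

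The calls of CEBPA, CEBPB and CEBPE overlapped. CEBPA and CEBPE shared 370 probe sets higher and 340 lower than vector, where independent lists would share 46.8 and 34.4, and 2 were called in opposite directions. CEBPA and CEBPB shared 229 higher and 232 lower (25.6 and 20.8 by independence; 2 opposite), and CEBPB and CEBPE 258 and 226 (33.5 and 20.1; 0 opposite). Of the 25 probe sets higher in CEBPD, 24 were also higher in CEBPA, 22 in CEBPE and 14 in CEBPB, against 1.79, 2.35 and 1.28 by independence. Simulated unchanged groups that shared the vector arrays gave 0 shared calls on average, and their fold changes correlated at about 0.50 across genes. With no group changed almost nothing is called, so that 0 does not measure how much the shared vector arrays add to the overlaps. The observed correlations, across genes that are not independent replicates, were 0.793 for CEBPA with CEBPE, 0.733 for CEBPA with CEBPB and 0.736 for CEBPB with CEBPE, and 0.497 to 0.527 for pairs with CEBPD. Covariances of CEBPD with CEBPA, CEBPB and CEBPE were 0.0817, 0.0597 and 0.0790, above the simulated 0.0323 to 0.0325. CEBPD moved the same way in 373 of the 413 probe sets called in CEBPA, CEBPB and CEBPE in 1 direction. The shared vector arrays also favour a common direction.

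Genes called higher in all 4 groups were Lpl, Cd1d1, Hp, Cxcl5, Fgf7, Aldh3a1, Glrx, Osmr, Pcdh7, Nus1, Xdh, Hmgcs1 and H2-M2, of which Xdh, Hmgcs1 and H2-M2 had the CEBPD calls described as fragile above, and Lpl and H2-M2 such calls in CEBPB. The other probe set of Lpl was called in CEBPA (log2 3.42) but not in CEBPB, CEBPD or CEBPE. Glrx, which encodes glutaredoxin, was higher by 1.97, 0.83, 0.91 and 1.96 on the log2 scale in CEBPA, CEBPB, CEBPD and CEBPE. Glrx, Osmr, Pcdh7 and Nus1 fall outside the naming rule and were named after their values were seen. Without CEBPD replicate 2, the overlaps of CEBPD with CEBPA, CEBPB and CEBPE were 13, 8 and 13, and without the arrays numbered 1 they were 10, 6 and 10; CEBPB and CEBPE then shared 255, CEBPA and CEBPB 235, and CEBPA and CEBPE 407. CEBPB and CEBPE shared 320 without vector replicate 3 and 305 without CEBPB replicate 3.

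Direct comparison of the C/EBPs set 2 sets of genes apart. Hspa1a, Hspa1b, Gadd45g, Gadd45b and Fos were highest in CEBPD and lowest in CEBPE, with ranges of 5.09, 4.24, 4.70, 3.96 and 4.10 on the log2 scale; Hspa1b averaged 67990 ± 6750 in CEBPD, 27890 ± 909 in CEBPB, 4653 ± 832 in CEBPA and 3600 ± 476 in CEBPE. Cd1d1, Hp, S100a8, Tgm3 and Pparg were highest in CEBPA. Cd1d1 averaged 9731 ± 485 there against 466 ± 173 in CEBPE, and Hp 38750 ± 8481 against 2534 ± 279. Pparg read 2983 ± 324 in CEBPA and was at the floor on all CEBPE arrays, and with no floor its difference among the C/EBPs was not called (adjusted p = 0.102, range over the alternatives 3.16e-09 to 0.102). In all, 709 probe sets differed among the 4 C/EBPs (limma F-test), 462 without CEBPD replicate 3, 405 without the arrays numbered 1 and 2010 with array weights.

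CEBPD and CEBPA differed in 585 probe sets (352 higher in CEBPD) and CEBPE and CEBPD in 572 (265 higher in CEBPE). Against CEBPA, 11 of 14 heat shock genes were higher in CEBPD and 12 over the list alone (median 0.75, adjusted p = 3.93e-15, and 0.0419 with an estimated correlation), as were 10 of 24 immediate early genes, 14 over the list alone (adjusted p = 1.03e-11, and 0.0419 with an estimated correlation). Acute phase genes were lower in CEBPD, with 3 of 8 called and 3 over the list alone (adjusted p = 0.00149, and 0.0419 with an estimated correlation). Against CEBPD, 11 heat shock genes were lower in CEBPE and 12 over the list alone (adjusted p = 1.28e-19, and 0.0474 with an estimated correlation). The count for CEBPD and CEBPA was 369 without CEBPA replicate 2, 382 without CEBPD replicate 3, 394 without the arrays numbered 1 and 930 with array weights. That for CEBPE and CEBPD was 343 without CEBPD replicate 3, 347 without CEBPE replicate 3, 374 without the arrays numbered 1 and 1506 with array weights.

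CEBPB differed from CEBPA in 199 probe sets (96 higher), and 3 of 8 acute phase genes were lower in CEBPB, 3 over the list alone (adjusted p = 1.57e-06, and 0.00614 with an estimated correlation). CEBPE differed from CEBPA in 91 (38 higher), where acute phase genes had 3 calls lower and 1 higher, and 3 and 2 over the list alone (adjusted p = 0.00502; adjusted p = 0.116 with an estimated correlation). CEBPE and CEBPB differed in 163 (73 higher), and 5 of 14 heat shock genes were lower in CEBPE, 9 over the list alone (median -0.39, adjusted p = 5.13e-12; adjusted p = 0.185 with an estimated correlation). CEBPD and CEBPB differed in 332 (185 higher), and 7 heat shock genes were higher in CEBPD, 12 over the list alone (adjusted p = 3.95e-12; adjusted p = 0.0704 with an estimated correlation). Without the arrays numbered 1 these 4 counts were 129, 38, 75 and 136, and under quantile normalization 299, 142, 283 and 580. With array weights CEBPB and CEBPA differed in 434, CEBPE and CEBPB in 950 and CEBPD and CEBPB in 1284. Single arrays moved 3 of them by more than 1.5 times. For CEBPE and CEBPA the count was 56 without CEBPA replicate 2, 51 without CEBPA replicate 3 and 55 without CEBPE replicate 3. For CEBPE and CEBPB it was 105, 102 and 93 without CEBPB replicates 1, 2 and 3 and 85 without CEBPE replicate 3. For CEBPD and CEBPB it was 199 without CEBPB replicate 2 or 3, and 217, 203 and 189 without CEBPD replicates 1, 2 and 3.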

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

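Of the tests in this part, all tests of the explanations weighed here were chosen after the result had been seen.

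The transferrin receptor gene Tfrc, which takes up iron, was higher in the mean of the 4 C/EBPs on control probe sets that the comparisons left out. Against vector, this mean was higher by 0.89 on the 3′ probe set of Tfrc (limma adjusted p = 3.26e-05), from 3204 ± 507 to 6016 ± 1277 (SD over 12 arrays of 4 groups). It was higher by 1.15 on the 5′ one (adjusted p = 0.00394) and by 1.46 on the middle one (adjusted p = 0.00229). In CEBPD alone none of these was called (0.48, 0.59 and 0.69, with adjusted p = 0.108, 0.452 and 0.452). The p-values of control probe sets given here were adjusted over the control probe sets of mouse genes alone, not over all tested probe sets. Probe sets of Tfrc among the tested genes were also higher, with adjusted p-values of 8.34e-04 and 9.87e-04. For the pyruvate carboxylase gene Pcx, the 3′ control probe set was higher in this mean by 0.47 (adjusted p = 0.00773) and a middle one by 1.46 (adjusted p = 0.00229). The 5′ one read 0.12 (adjusted p = 0.612) and the other middle one 0.18 (adjusted p = 0.505). Neither of the higher Pcx probe sets was called in CEBPB (adjusted p = 0.7117 and 0.0664) or in CEBPD (0.7735 and 0.4518).

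The heat shock genes were lower in CEBPA, CEBPB and CEBPE than in vector and CEBPD, although with an estimated correlation the list was not called for CEBPB against vector (adjusted p = 0.0643) or CEBPD against CEBPB (0.0704; 7 of 14 genes called). That the vector arrays alone stood apart is argued against by CEBPD, whose heat shock genes lay a median of 0.75 above those of CEBPA, past the threshold. The CEBPD list itself read a median of -0.23 against vector, called by camera only with the preset correlation (adjusted p = 0.680 when estimated). High vector arrays as a part of the difference were therefore not excluded. RNA quality is argued against by the actin and Gapdh controls, whose log2 3′ to 5′ ratio differed by 0.0243 between the vector and CEBPD arrays and the other 9. A lower metal load cannot be told apart from an effect of the expressed C/EBP, since the zinc exporter gene Slc30a1 was lower than in vector by a mean of -0.87 over these 3 groups, lower in CEBPA and CEBPB than in CEBPD (adjusted p = 0.0184 and 0.0115), and not called between CEBPE and CEBPD (0.127). For the lower heat shock genes of CEBPE against CEBPB (5 of 14 called, list adjusted p = 0.185 with an estimated correlation), metal load is argued against only weakly. Slc30a1, a lone gene, read 0.36 higher in CEBPE (SE 0.18) and was not called (adjusted p = 0.384). An effect of the factor is a hypothesis that was not tested.

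CEBPD had few called probe sets. Its arrays were not noisier by the median SD within the group, which was 0.846 of the mean over the other C/EBP groups (0.180 in CEBPD, 0.207 in CEBPA). The fit estimated 1 spread per probe set over all groups. Noise in the CEBPD arrays would thus have widened the standard errors of every group, so the SD cannot decide why CEBPD had fewer calls. Changes as large as those of CEBPA that missed the threshold are argued against by the 585 probe sets called between CEBPD and CEBPA. Smaller changes are not excluded. Over the CEBPA calls, CEBPD changed by a median of 0.210 on the log2 scale in the CEBPA direction, and CEBPA by 0.791. The vector arrays shared by both contrasts favour a common direction. A lower amount or activity of the introduced C/EBPδ could account for the few calls as well as a property of the factor, and neither was tested.

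The arrays numbered 1 deviated together in all groups, with 159 probe sets higher and 715 lower of 6963. With the preset correlation, camera called ribosomal protein (median -0.30, adjusted p = 2.87e-04), oxidative phosphorylation (-0.21, 0.00447) and glycolysis genes (-0.23, 0.0271) lower on these arrays. Muscle markers were called higher on them (0.15, 0.0333). Without these arrays the ribosomal call for the mean of the 4 and the oxidative phosphorylation call of CEBPB held at the preset correlation (0.0246 and 0.0158). Over all arrays neither was called with an estimated correlation (adjusted p = 0.647 and 0.647) or by fry (0.291 and 0.139). Hybridisation or scanning was examined through bacterial control RNAs, which on these arrays differed by -0.28 on the log2 scale from the other arrays. An exact permutation within groups gave a two-sided p of 0.0206 (243 choices, smallest possible p 0.00412), and the controls were the lowest of their group in 3 of 5 groups. The array medians used to scale these controls were not matched to their own arrays, so the difference and its p-value are not those of scaled signals. A difference in scanner gain would also be removed by the authors' scaling to a common mean. The source therefore stays open. Lower RNA quality is argued against by the log2 3′ to 5′ ratio of actin and Gapdh, which degraded RNA would raise and which differed by -0.0917 from the other arrays (exact permutation within groups, two-sided p = 0.0370). A biological explanation was not tested, and the counts without these arrays stand beside each comparison.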

How the results depend on the processing

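The alternative without the arrays numbered 1 was chosen after the data had been seen, and all others in this part were planned. No call of a named gene or list turned to the other direction under any alternative run. Scaling by the ratio to the mean array did turn the majority of higher calls, from 50.1% to 47.7% in CEBPA, from 55.1% to 49.0% in CEBPB and from 57.6% to 47.0% in CEBPE. Of 341 combinations of a named gene and contrast and 130 of a list and contrast, the settings other than leaving out 1 array gave 3712 gene results on the same side of the threshold, 70 weaker and 110 stronger, and 1649 list results on the same side, 63 weaker and 67 stronger. Leaving out each array in turn gave 4916 gene results on the same side, 146 weaker and 23 stronger, and 1897, 22 and 31 for lists. Signal under the floor and filter limits what dim genes can show. Where a setting leaves out arrays, fewer samples enter the test; otherwise the cause was not tested.

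Without the arrays numbered 1 the counts against vector were 642 for CEBPA, 348 for CEBPB, 11 for CEBPD, 692 for CEBPE and 518 for the mean of the 4. They were 129 (CEBPB and CEBPA), 38 (CEBPE and CEBPA), 136 (CEBPD and CEBPB), 75 (CEBPE and CEBPB) and 374 (CEBPE and CEBPD) between factors, 685 for the 5 groups and 405 for the 4 C/EBPs. Overlaps were 235 (CEBPA and CEBPB), 10 (CEBPA and CEBPD), 407 (CEBPA and CEBPE), 6 (CEBPB and CEBPD), 255 (CEBPB and CEBPE) and 10 (CEBPD and CEBPE), and 3 lists were called in CEBPD.

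With array weights the counts were 1576 for CEBPB, 74 for CEBPD and 1730 for CEBPE against vector, 434 (CEBPB and CEBPA), 930 (CEBPD and CEBPA), 1284 (CEBPD and CEBPB), 950 (CEBPE and CEBPB) and 1506 (CEBPE and CEBPD), 2442 for the 5 groups and 2010 for the 4 C/EBPs. Overlaps were 773 (CEBPA and CEBPB), 62 (CEBPA and CEBPD), 54 (CEBPB and CEBPD), 933 (CEBPB and CEBPE) and 61 (CEBPD and CEBPE).

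With the replicate number as a block the counts were 1099 for CEBPB, 44 for CEBPD and 1408 for the mean of the 4, 347 (CEBPB and CEBPA), 990 (CEBPD and CEBPA), 171 (CEBPE and CEBPA), 684 (CEBPD and CEBPB), 310 (CEBPE and CEBPB) and 1037 (CEBPE and CEBPD), 1820 for the 5 groups and 1252 for the 4 C/EBPs. Under this block, overlaps were 764 (CEBPA and CEBPB), 40 (CEBPA and CEBPD), 31 (CEBPB and CEBPD), 804 (CEBPB and CEBPE) and 38 (CEBPD and CEBPE), and 8 lists were called in CEBPD. With the block Hspg2 was called lower in CEBPD (adjusted p = 0.0441), Cebpb lower in CEBPA, CEBPE and the mean of the 4 (log2 -0.58, -0.54 and -0.45; adjusted p = 0.00263, 0.00459 and 0.00389), and the S phase list in CEBPA (adjusted p = 0.0409). With an estimated correlation and no block the S phase list was not called in CEBPA (adjusted p = 0.595). The labels do not say that equal numbers were processed together. Deviations from the group mean correlated across genes at 0.22 to 0.44 between arrays numbered 1, 0.02 to 0.43 between those numbered 2 and -0.07 to 0.12 between those numbered 3, and 13 of 15 arrays were closest to their own number.

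Quantile normalization gave 39 for CEBPD, 299 (CEBPB and CEBPA), 142 (CEBPE and CEBPA), 580 (CEBPD and CEBPB) and 283 (CEBPE and CEBPB), and overlaps of CEBPD of 37 with CEBPA, 25 with CEBPB and 35 with CEBPE. No further scaling gave 142 (CEBPE and CEBPA), 526 (CEBPD and CEBPB), 253 (CEBPE and CEBPB), an overlap of 22 (CEBPB and CEBPD) and 9 lists in CEBPD. Scaling by the ratio to the mean array gave 139 (CEBPE and CEBPA), 245 (CEBPE and CEBPB) and 9 lists in CEBPD. Only the groups of the contrast gave 15 for CEBPD and 690 for CEBPE, and a threshold of 0.1 an overlap of 22 (CEBPB and CEBPD). With the correlation estimated, 4 lists were called in CEBPA, 1 in CEBPB, 0 in CEBPD, 2 in CEBPE and 2 for the mean of the 4, where the preset gave 10, 12, 5, 9 and 11; fry called 3 in CEBPD.

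Leaving out 1 array gave 743 to 1029 for CEBPA, 372 to 694 for CEBPB, 13 to 29 for CEBPD, 751 to 1151 for CEBPE and 500 to 948 for the mean of the 4. Between factors the ranges were 138 to 220 (CEBPB and CEBPA), 369 to 627 (CEBPD and CEBPA), 51 to 109 (CEBPE and CEBPA), 189 to 380 (CEBPD and CEBPB), 85 to 182 (CEBPE and CEBPB) and 343 to 625 (CEBPE and CEBPD). They were 904 to 1140 for the 5 groups and 462 to 772 for the 4 C/EBPs. Overlaps ranged from 311 to 484 (CEBPA and CEBPB), 13 to 26 (CEBPA and CEBPD), 494 to 706 (CEBPA and CEBPE), 8 to 17 (CEBPB and CEBPD), 305 to 486 (CEBPB and CEBPE) and 13 to 25 (CEBPD and CEBPE). Lists called ranged from 10 to 11 in CEBPA, 10 to 15 in CEBPB, 4 to 7 in CEBPD, 8 to 11 in CEBPE and 10 to 12 for the mean of the 4. The lone removals that moved a count by more than 1.5 times were vector replicate 3 (420 for CEBPB, 751 for CEBPE, 500 for the mean of the 4, 320 shared by CEBPB and CEBPE), vector replicate 1 (603 for the mean of the 4) and CEBPD replicate 2 (13 for CEBPD, overlaps of 13, 8 and 13 with CEBPA, CEBPB and CEBPE, 203 for CEBPD and CEBPB). CEBPD replicate 3 gave 382 (CEBPD and CEBPA), 189 (CEBPD and CEBPB), 343 (CEBPE and CEBPD) and 462 for the 4 C/EBPs, and CEBPD replicate 1 gave 217 (CEBPD and CEBPB). CEBPA replicate 2 gave 369 (CEBPD and CEBPA) and 56 (CEBPE and CEBPA), and CEBPA replicate 3 gave 51 (CEBPE and CEBPA). CEBPB replicate 1 gave 105 (CEBPE and CEBPB), replicate 2 gave 418 for CEBPB, 199 (CEBPD and CEBPB) and 102 (CEBPE and CEBPB), and replicate 3 gave 372 for CEBPB, 199, 93 and an overlap of 305 with CEBPE. CEBPE replicate 3 gave 55 (CEBPE and CEBPA), 85 (CEBPE and CEBPB) and 347 (CEBPE and CEBPD).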

Other observations

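Of the tests in this part, the test of granulocyte genes was chosen after the result had been seen. Chemokine genes went both ways. Cxcl5 and Cxcl1, which attract neutrophils, rose in CEBPE 5.03-fold and 2.96-fold, while Ccl8 fell from 7020 ± 448 to 3531 ± 558, Ccl9 2.34-fold and Il11 7.24-fold (1 CEBPE array at the floor); of 11 measured cytokine genes, 3 rose and 4 fell in CEBPE, 2 and 4 in CEBPA, 2 and 4 in CEBPB and 2 and 0 in CEBPD (adjusted over the list alone 4 and 4, 2 and 5, 3 and 4, and 4 and 1), and with the settings of the report camera called the list in none of them. In CEBPD it called the cytokine list with the filter at the 70th percentile (adjusted p = 1.50e-04) and under each other scaling (0.0447 to 0.0492), but not with no filter (0.496) or with an estimated correlation (0.707). Igf2, a fetal growth factor gene, fell 5.44-fold in CEBPE, from 5570 ± 343 to 1046 ± 264, and 1.54-fold in CEBPA. Nr1d1 fell 3.27-fold in CEBPA and 3.23-fold in CEBPE. Id3 fell 4.05-fold in CEBPA and 2.74-fold in CEBPE. Of 22 glycolysis and hypoxia genes, 7 rose and 4 fell in CEBPA and 7 and 3 in CEBPE (adjusted over the list alone 8 and 4 in either), and camera called the list after quantile normalization (adjusted p = 0.0152 and 0.0334) but not under median scaling (0.149 and 0.289, and 0.691 and 0.762 with an estimated correlation); the phosphofructokinase gene Pfkl rose 2.70-fold in CEBPA and 2.52-fold in CEBPE, and the neuronal enolase gene Eno2 fell 2.02-fold and 2.61-fold. Cd68, a lysosomal protein gene that marks macrophages, fell 4.05-fold in CEBPA and 2.77-fold in CEBPE, and to 1552 ± 172 from 3103 ± 244 in CEBPB; of 8 macrophage and leukocyte markers it was the 1 called in CEBPA and CEBPB, and in CEBPA fry called that list (adjusted p = 0.00526) while camera did not (0.229).

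Among 23 oxidative stress genes, 4 rose and 4 fell in CEBPA and 4 and 2 in CEBPE (adjusted over the list alone 4 and 6, and 4 and 4), where Sod3, extracellular superoxide dismutase, rose 3.23-fold. Interferon response genes had 2 rises and 2 falls among 19 in CEBPA, 3 and 0 in CEBPB and 1 and 2 in CEBPE. Cell adhesion and receptor genes had 2 rises and 8 falls among 26 in CEBPA, 3 and 1 in CEBPB and 3 and 2 in CEBPE. S phase genes had 1 rise and 2 falls among 29 in CEBPA, 1 and 0 in CEBPB and 2 and 1 in CEBPE. The insulin-like growth factor list had 2 rises and 2 falls among 11 in CEBPA and 1 and 1 in CEBPE. Muscle markers had 1 fall among 9 in CEBPB and in CEBPE. Adjusted over the list alone, the interferon and insulin-like growth factor counts were the same, those of cell adhesion were 3 and 8, 3 and 1, and 3 and 4, those of S phase 1 and 2, 1 and 0, and 1 and 0, and muscle markers had 1 fall in CEBPB and none in CEBPE. Vwf was the 1 of 4 endothelial markers called, lower in CEBPA, CEBPB and CEBPE, and none of the 2 epithelial and 2 hepatocyte genes measured was called; these lists were too small for camera. With the settings of the report camera called none of the larger lists of this paragraph against vector. With no filter it called the S phase and oxidative stress lists in CEBPA (adjusted p = 0.0290 and 0.0297, and 0.490 and 0.276 with an estimated correlation), with the filter at the 70th percentile the cell adhesion list in CEBPA (0.00902), after quantile normalization S phase in CEBPA (0.0434) and the interferon list in CEBPB (0.0440), and after scaling by the ratio to the mean array S phase in CEBPA (0.0488). The interferon list in CEBPB also passed by fry (0.0141). With the filter of the report and an estimated correlation, the adjusted p-values of S phase, oxidative stress and cell adhesion in CEBPA and of the interferon list in CEBPB were 0.595, 0.526, 0.526 and 0.423. The median, mean and test of a list differed in sign in 1 of 26 lists in CEBPA, 2 in CEBPB, 6 in CEBPD and 6 in CEBPE, and 0 of these were called.

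Per2, a clock gene that the study is known for, lay under the signal filter. With no filter it was at least 1.96 higher on the log2 scale in CEBPE (747 ± 135 against 90.2 ± 85.3, all vector arrays being at the floor; limma adjusted p = 0.00336), while CEBPA read 346 ± 182 (adjusted p = 0.237). The difference between CEBPE and CEBPA was not called (adjusted p = 0.189). The circadian list was written with this gene known, so its direction is not independent evidence.

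C/EBPε acts in granulocytes, and whether it raised their genes in fibroblasts was asked with no signal filter. Camera did not call the 24 granulocyte genes in CEBPE (adjusted p = 0.759; 1 higher, S100a8), nor in CEBPA (adjusted p = 0.290; 5 higher and 1 lower). Among the 7 granulocyte genes that passed the filter, 3 were higher and 1 lower in CEBPA, where camera did not call the list (adjusted p = 0.230) and fry did (6.48e-04). A gene passed the filter if 3 arrays were bright, so a rise in CEBPA could itself bring it in. The fry result on these genes is therefore not independent evidence. With no filter the 5 higher in CEBPA were S100a8, Lyz2, S100a9 (1 vector array at the floor), Ngp (all vector arrays at the floor) and Camp. Between CEBPE and CEBPA, S100a8 differed by -2.61 (adjusted p = 0.00114), Lyz2 by -1.72 (0.0209) and S100a9 by -1.42 or beyond, all CEBPE arrays being at the floor (0.0266), while Ngp (-0.55, 0.282) and Camp (-0.32, 0.892) were not called. The list holds many genes near the floor, so a small rise in CEBPE could not be excluded.

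The arrays were also split into other groups of the same sizes, which mixes arrays of the real groups, and fitted again. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 997 (CEBPA), 648 (CEBPB), 25 (CEBPD) and 1134 (CEBPE) against vector, and the highest of the other splits 2, 0, 0 and 0; between factors the real counts were 199 (CEBPB and CEBPA), 585 (CEBPD and CEBPA), 91 (CEBPE and CEBPA), 332 (CEBPD and CEBPB), 163 (CEBPE and CEBPB) and 572 (CEBPE and CEBPD), and the highest others 0, 0, 2, 1, 0 and 1. For lists the real counts were 10, 12, 5 and 9 in CEBPA, CEBPB, CEBPD and CEBPE, and the highest others 7, 10, 4 and 8. Of 100 splits of all arrays, the real one included, only the real one reached the count for the mean of the 4 C/EBPs against vector (913, highest other 85). The same held for the 5 groups (1149, highest other 15) and, over the C/EBP arrays, for the 4 C/EBPs (709, highest other 220). Arrays falling into groups at random would thus rarely give these counts. The mixing widens the spread in the fit and lowers the counts of the other splits. Such splits cannot exclude differences between cultures that came with the groups for other reasons. For the 11 lists called for the mean of the 4, 7 of 100 splits, the real one included, gave as many (highest other 13), so chance was not excluded.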
